A study of Homo sapiens with 6 samples.

How the data were processed

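RNA was sequenced from primary human umbilical vein endothelial cells (HUVEC) of 3 donors, named A, B and C here. Cells of each donor were cultured for 48 h with 0.5 µM SR1 (StemRegenin 1, labelled as an inhibitor of the canonical aryl hydrocarbon receptor, AHR, pathway) or with the DMSO vehicle alone at 1:10000, which gave 6 libraries, 3 per group. Per the labels' protocols, the libraries were strand-specific and made from polyadenylated RNA after on-column DNase treatment.

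The first deposited table holds FPKM, fragments normalised for gene length and library size, for 17582 genes in the 6 libraries, as the authors made them. The authors' ratio column in the same table was recomputed and equals the mean SR1 FPKM plus 1 divided by the mean vehicle FPKM plus 1. The second table is the authors' own paired comparison of 60642 genes, with a log2 fold change and a log2 mean abundance per gene, a likelihood ratio score and a p-value with its false discovery rate (FDR), per the file headers. Of those genes, 15402 share its lowest abundance. The submitters' processing notes name GRCh38, STAR, featureCounts and edgeR, without versions or settings. Whether the counting used strand is not given in the sources used here, so values of antisense and overlapping genes are uncertain, as are those of genes with near-identical copies such as HSPA1A and HSPA1B.

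The FPKM of 17571 genes (99.94%) were whole multiples of the value of 1 read, within a tolerance of 0.001, so whole reads per gene were recovered from them. The recovered reads in listed genes numbered 55564002 (vehicle) and 71397308 (SR1) for donor A, 51312096 and 55611627 for donor B, and 51796789 and 56564102 for donor C. The implied gene lengths equalled the merged exon length of GENCODE release 29 for 92.8% of genes, and all 17582 gene identifiers matched that release, from which coordinates (GRCh38), gene types and exon overlaps were taken. The implied library totals were larger than the reads in listed genes in every library. Read recovery, library totals and identifier matching started from all genes of the table. After that, 51 genes that can tell about a donor were left out of the comparison, its alternatives and the list tests.

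The comparison used limma 3.58.1 in R 4.3.3 with statmod 1.5.0, on log2(FPKM + 0.1), with a donor term and moderated variances with a trend and robust estimation, over the 12796 genes with FPKM of 0.5 or more in at least 3 libraries. Adjusted p-values are Benjamini-Hochberg values, the tests are two-sided, and the threshold was 0.05. Fold changes are on the log2(FPKM + 0.1) scale, which understates the change of low genes. Standard errors (SE) are those of limma, and the SD is over the 3 donors. The design foresaw a count test had the table held raw counts. Since it holds FPKM, limma was the main test. Limma's voom on the recovered reads was added as an alternative after the data were seen. It was run once over the same genes and once over all genes with 20 or more reads in the 6 libraries together. Both runs left out genes whose reads were not recovered, so voom says nothing about those. In the first run 15 of 18 tested TGF beta, 13 of 14 coagulation and 11 of 13 mitochondrially encoded list members remained. Voom values of single genes are from the second. They were looked up for named genes, for list members below the filter and for genes and groups examined afterwards. Other list members above the filter were not looked up there.

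The pairing of libraries by donor comes from the labels. As a check, the deviations of each library from its group mean were correlated across genes, which are not independent replicates. The same-donor correlations were 0.744, 0.863 and 0.866, and those of different donors lay between -0.229 and -0.571. Deviations from a group mean cancel out within the group, so positive same-donor values make those of different donors negative on balance. The negative values are therefore no separate evidence of pairing. The median SD of a gene between donors was 0.201 in vehicle and 0.171 in SR1 libraries on the log2 scale, and that of the paired differences was 0.116. The libraries came from 3 separate donors and the main fit has a donor term. Its p-values therefore rest on how the paired differences vary between donors, with variances moderated across genes.

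Before the data were examined, 28 gene lists were fixed, of which 23 had 5 or more tested members and were tested with camera at a preset correlation of 0.01, then again with an estimated correlation and with fry. Camera compares a list with the other genes. Fry asks whether its members move, on balance, one way. The mixed form of fry asks whether they move in either direction. Also fixed were the genes to be named: among protein-coding genes past the threshold, changed the same way in all 3 donors and with a mean FPKM of 1 or more in the higher group, the 12 largest in each direction, filled by the smallest p-values where fewer passed, plus up to 4 members of each list with the smallest p-values and all AHR target genes. The alternatives tried were no donor term, each donor left out in turn, pseudocounts of 1 and 0.01, no filter and a stricter filter, 2 other scalings, limma without trend and robust estimation, and a threshold of 0.1.

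The procedure was tested on simulated data for the comparison of SR1 with vehicle over 12782 genes, of which 198 were changed. It recovered 18.4% of genes changed by 0.3 on the log2 scale, 77.6% of those changed by 0.5, 98% of those changed by 1 and 96% of those changed by 2, and 12 of 156 calls (7.7%) were false. The simulated dispersion of 0.004 was assumed and was the same for every gene, and each change had the same size in all donors. Recovery of real genes, whose spread and response can differ between donors, may be lower. Figures were drawn with matplotlib.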

Results

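Gene expression was compared in HUVEC, primary endothelial cells of the umbilical vein, after 48 h with 0.5 µM SR1 or with DMSO vehicle. SR1 is labelled as an inhibitor of the canonical pathway of AHR, a ligand-activated transcription factor that induces xenobiotic-metabolising enzymes. Cells of 3 donors each received both treatments, so 3 SR1 and 3 vehicle libraries formed 3 pairs. The libraries held from 51312096 to 71397308 recovered reads in listed genes, with the deepest being the SR1 library of donor A. Values below are mean FPKM ± SD (n = 3 donors) and log2 fold changes of SR1 over vehicle ± SE.

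CYP1A1, the cytochrome P450 enzyme classically induced through AHR, had the largest fall. It went from 5.10 ± 1.64 FPKM in vehicle to 0.0538 ± 0.0231 FPKM under SR1, a log2 fold change of -5.04 ± 0.168 (limma, adjusted p = 2.74e-04), and lay lower in all 3 donors. VIPR1, a receptor for vasoactive intestinal peptide, went from 1.37 ± 0.297 to 0.114 ± 0.0356 FPKM (log2 fold change -2.77 ± 0.153), and ITGA11, the collagen-binding integrin alpha 11 subunit, from 1.96 ± 1.00 to 0.220 ± 0.116 FPKM (-2.59 ± 0.208). GJA4, which encodes the arterial gap junction protein connexin 37, was the only gene that rose, from 7.45 ± 7.19 to 11.5 ± 11.6 FPKM, and did so in each donor (log2 fold changes 0.53, 0.66 and 0.53). In all, 17 of 12796 genes changed by limma at an adjusted p under 0.05, of which 1 rose and 16 fell, each in the same direction in all 3 donors. All 17 were protein-coding, and 7 of the 16 fell at least 2-fold.

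The count depended on the test and on single donors. It was 119 without donor A, 9 without donor B and 0 without donor C (1 without the donor term), and 136 with voom on the recovered reads. With each library scaled to one sum, 170 genes were called, among them all 17, and 23.5% of the calls were higher under SR1, against 5.9% in the main comparison.

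Among the other genes that fell were both PLA2G4A, the cytosolic phospholipase A2 that releases arachidonic acid, and PTGS2 (cyclooxygenase 2), which converts it to prostaglandin H2. PLA2G4A went from 5.46 ± 1.22 to 2.46 ± 1.04 FPKM (log2 fold change -1.17 ± 0.102, limma adjusted p = 0.0196) and PTGS2 from 2.63 ± 0.671 to 1.25 ± 0.113 FPKM (-0.996 ± 0.111, adjusted p = 0.0423). SHISA2, a regulator of Wnt and FGF receptor maturation, and the sialyltransferase ST8SIA6 had log2 fold changes of -1.42 ± 0.129 and -1.23 ± 0.133. LIPG (endothelial lipase) went from 4.06 ± 0.778 to 2.08 ± 0.413 FPKM, and ADAMTS18, a secreted metalloprotease, from 28.7 ± 6.01 to 16.3 ± 2.65 FPKM. SERPINB2 (plasminogen activator inhibitor 2) went from 24.2 ± 14.3 to 14.1 ± 7.95 FPKM with a log2 fold change of -0.76 ± 0.053, and its log2 fold changes in the 3 donors were -0.71, -0.81 and -0.75. LRP5, a Wnt co-receptor, and TNFAIP8L3 fell by 0.71 and 0.70 on the log2 scale.

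**Figure D1:**
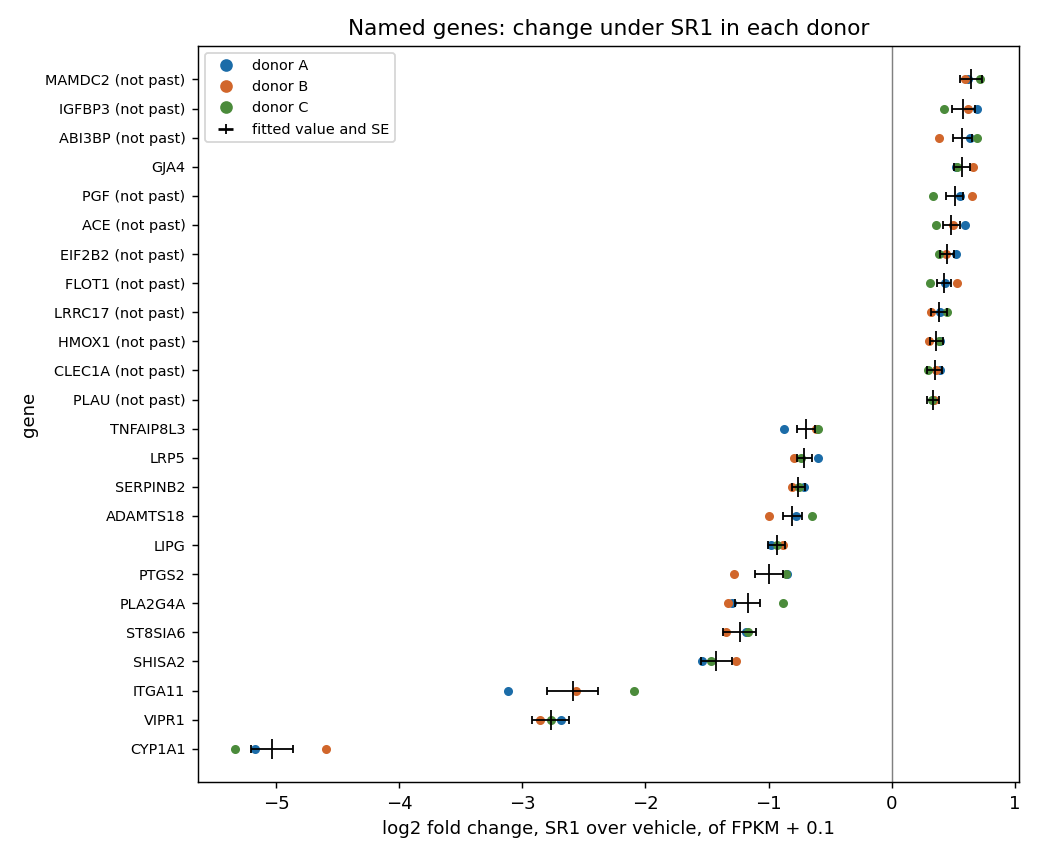
Log2 fold change of SR1 over vehicle (x axis, on FPKM + 0.1) for the 24 genes of the naming rule (y axis); points are the 3 donors and bars the limma estimate ± SE. CYP1A1 lies at -5.04, all 12 genes on the lower side passed the threshold, and on the higher side only GJA4 did.

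On the higher side only GJA4 passed, so the remaining places went to the genes with the smallest p-values, none of which passed in limma. Nearest was EIF2B2, a subunit of a translation initiation factor complex, at 21.8 ± 2.98 and 29.9 ± 4.78 FPKM (log2 fold change 0.45 ± 0.054, adjusted p = 0.0506). The extracellular matrix gene ABI3BP had a log2 fold change of 0.58 ± 0.077, MAMDC2 of 0.65 ± 0.088, and PGF (placental growth factor) of 0.51 ± 0.07, each with an adjusted p of 0.0711. FLOT1 (0.43), HMOX1 (0.36), ACE (0.48), PLAU (0.34), IGFBP3 (0.58), CLEC1A (0.35) and LRRC17 (0.39) had positive log2 fold changes in all 3 donors and did not pass in limma. With voom on the recovered reads all 12 genes of the higher side passed, with adjusted p from 0.00123 (ABI3BP) to 0.0429 (LRRC17).

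The AHR target genes asked how far the pathway named in the labels moved. Of 12 listed targets 9 were tested, and 1, CYP1A1, fell in limma over all genes tested. Adjusted over the list alone, 5 fell and 1 rose. AHRR, the AHR repressor, had 4.18 ± 0.585 and 2.78 ± 0.293 FPKM (log2 fold change -0.57 ± 0.066, limma adjusted p = 0.0506). TIPARP, the ADP-ribosyltransferase that restrains AHR, had -0.52 ± 0.071 (0.0711), ALDH1A3, a retinal dehydrogenase, -0.56 ± 0.082 (0.0758), and NQO1 -0.21 ± 0.067 (0.512). Voom passed AHRR (adjusted p = 8.93e-04), TIPARP (0.00247) and ALDH1A3 (0.00247). The other tested targets had log2 fold changes of 0.25 for LMCD1, 0.12 for CYP2S1, 0.11 for SLC7A5 and -0.15 for STC2, none past the threshold over all genes in either test. In the authors' deposited table AHRR had a log2 fold change of -0.37 (FDR 0.0164). That table also calls CYP1A1 (FDR 1.47e-288), CYP1B1 (6.78e-74), TIPARP (7.18e-06) and ALDH1A3 (5.34e-06) as lower, and none of the other targets.

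CYP1B1, another P450 induced through AHR, lay below the filter, since its FPKM was 0.478 ± 0.326 in vehicle and 0.00638 ± 0.00419 under SR1. Its recovered reads were 182, 259 and 48 in the vehicle libraries and 5, 2 and 1 in the SR1 libraries of donors A, B and C. With voom on the recovered reads of genes with 20 or more, its log2 fold change was -5.85 ± 0.447 (adjusted p = 3.54e-05). Without the filter, the FPKM comparison by limma gave an adjusted p of 0.301. ALDH3A1 and SCIN, also below the filter, had 0.047 ± 0.0237 and 0.0162 ± 0.00781 FPKM in vehicle and voom log2 fold changes of -0.27 ± 0.429 and 0.05 ± 0.363. CYP1A2 and UGT1A6 appear only in the authors' deposited table, both with an FDR of 1.

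**Figure D2:**
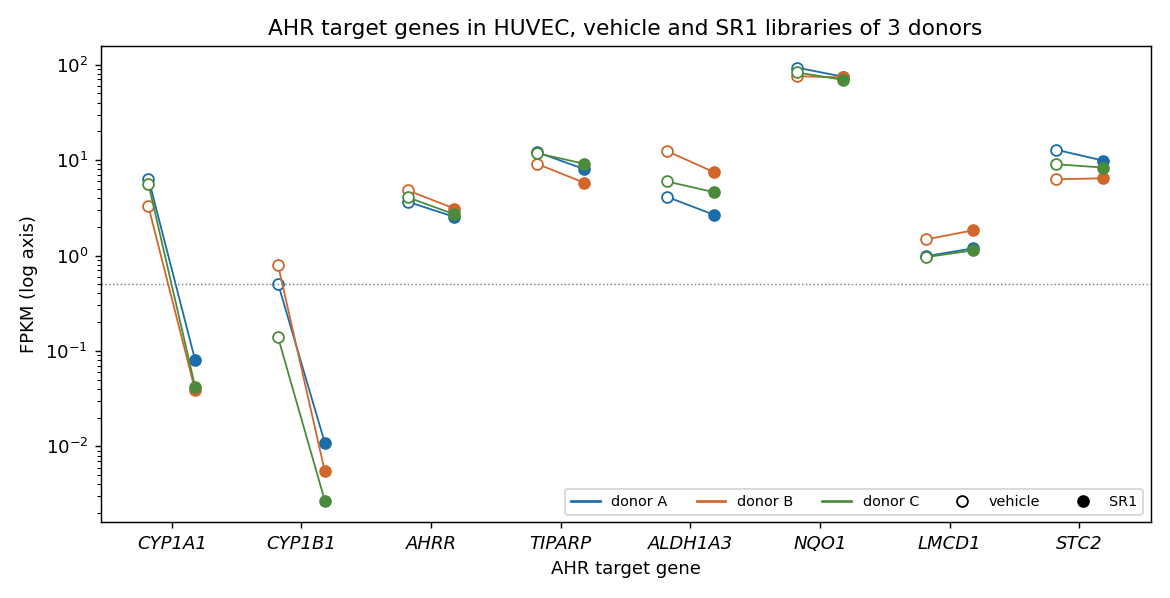
FPKM (y axis, log scale) of 8 AHR target genes (x axis) in the vehicle (open) and SR1 (filled) library of each of 3 donors, joined by donor; the dotted line marks the filter of 0.5 FPKM. CYP1A1 and CYP1B1 lie lower under SR1 in all 3 donors, with mean FPKM of 5.10 against 0.0538 and 0.478 against 0.00638, while the other 6 genes change far less.

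As a group, the AHR targets lay lower than other genes under SR1 (camera, adjusted p = 8.22e-04), though camera with an estimated correlation gave an adjusted p of 0.83 for them and for the other 4 lists that passed. Fry, which asks whether the members move one way on balance, gave an adjusted p of 0.0179 for the AHR targets, and did not pass for the Notch and arterial (0.196), venous and lymphatic (0.0975), vasoactive (0.599) and interferon (0.599) lists. Without CYP1A1 the remaining 8 still passed camera (adjusted p = 0.0262). Their median log2 fold change was -0.18.

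The Notch and arterial list lay higher (camera adjusted p = 0.0193; adjusted p = 0.83 with an estimated correlation; median log2 fold change 0.16), a call lost without the donor term (adjusted p = 0.117). Of 14 tested members 1, GJA4, rose in limma, and 6 rose and 1 fell adjusted over the list alone. LFNG, which modifies Notch receptors, had 1.95 ± 0.306 and 2.91 ± 0.211 FPKM (log2 fold change 0.56), and the Notch effectors HES1 and HEY1 had 0.38 and 0.43, whereas HEY2 had -0.74, all short of the threshold over all genes in limma. Voom passed LFNG (adjusted p = 0.0186), HES1 (0.0354) and HEY2 (0.0222). The venous and lymphatic list lay lower (camera adjusted p = 0.0466; adjusted p = 0.83 with an estimated correlation), with 0 of 7 members past the threshold in limma, NRP2 at -0.45 (voom adjusted p = 0.00247) and NR2F2, a regulator of venous identity, at -0.16. Its call was lost in most other settings: without donor A (camera adjusted p = 0.05002), without donor C (0.192), without the donor term (0.117), with a pseudocount of 1 (0.0553), with no filter (0.137), with one sum (0.056), without trend and robust estimation (0.0955) and in both voom fits (0.051 and 0.145).

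The vasoactive factors lay lower (camera adjusted p = 0.0193; adjusted p = 0.83 with an estimated correlation), with 1 of 8 members, PTGS2, past the threshold in limma. PTGS1 had a log2 fold change of -0.29 and EDN1 (endothelin 1) of -0.11, while ACE had 0.48 and passed in voom (adjusted p = 0.00247). Below the filter, the endothelin receptor EDNRB also passed in voom, with a log2 fold change of -0.71 ± 0.145 (adjusted p = 0.041). The camera call of the vasoactive list was lost without donor B (0.153) or donor C (0.156). The type I interferon response lay higher (camera adjusted p = 0.00428; adjusted p = 0.83 with an estimated correlation), with 0 of 15 members past the threshold in limma and 13 of 15 positive. The authors' deposited table calls MX1 (FDR 0.03) among them, and MX2 (0.0146) and IFI44L (0.0407) below the filter. IFI44 had a log2 fold change of 0.30, IFI35 of 0.30, ISG20 of 0.33 and ISG15 of 0.23. The median of the list was 0.08 in donor A, 0.35 in donor B and 0.04 in donor C, and without donor B the adjusted p was 0.362.

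**Figure D3:**
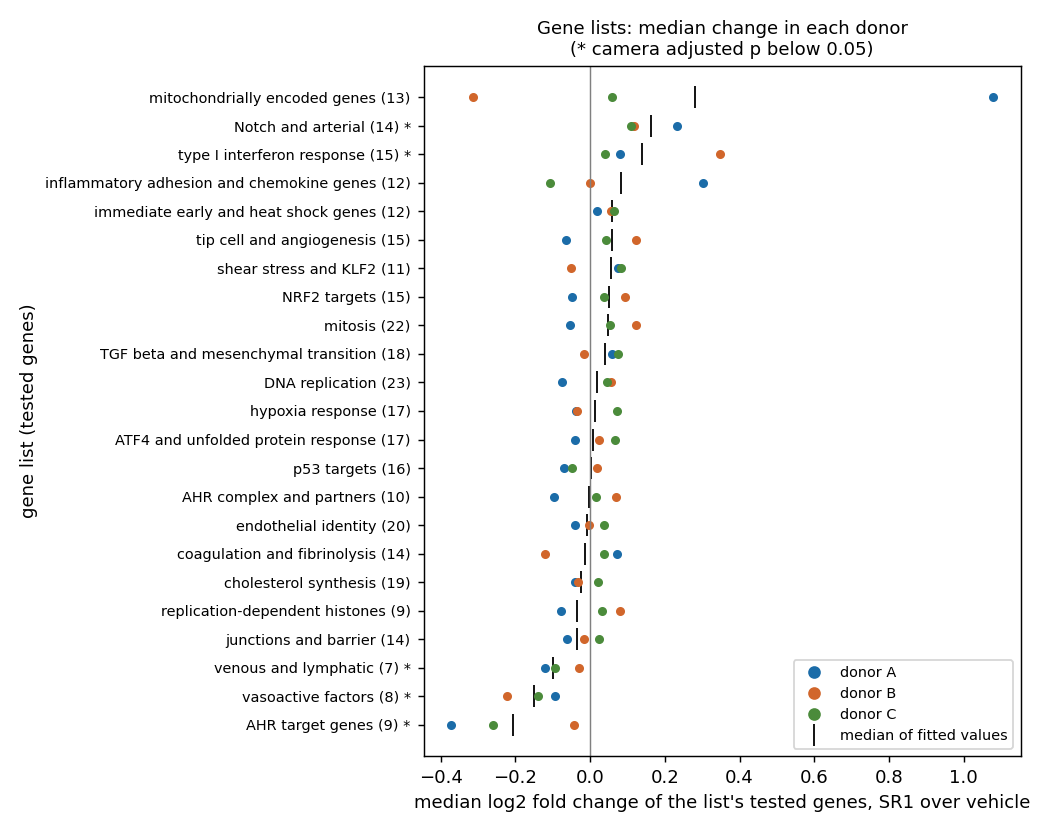
Median log2 fold change of SR1 over vehicle (x axis) of the tested genes of 23 fixed gene lists (y axis, with the number tested); points are the 3 donors, bars the median of the fitted values and stars a camera adjusted p under 0.05. The AHR targets have the lowest median, -0.21, and the mitochondrially encoded genes part the donors, with 1.08 in donor A, -0.31 in donor B and 0.06 in donor C.

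Endothelial identity genes did not differ as a group, with 0 of 20 past the threshold in limma (camera adjusted p = 0.627) and a median log2 fold change of -0.01. PECAM1 (334.5 ± 71.5 and 330.2 ± 68.6 FPKM) and CDH5 (342.3 ± 79.6 and 348.6 ± 78.4 FPKM) went both ways across the donors. MMRN1 (log2 fold change -0.50), KDR (the VEGF receptor 2; -0.28) and VWF (-0.27) lay lower in all 3 donors and did not pass over all genes in limma, though they did in voom (adjusted p = 0.0106, 0.0325 and 0.0403). AHR itself had 3.15 ± 0.517 and 3.09 ± 0.127 FPKM, and 0 of 10 tested genes of the AHR complex and its partners passed in limma (camera adjusted p = 0.615). None of the 22 mitosis genes (adjusted p = 0.236) or the 23 DNA replication genes (0.705) passed in limma, with MKI67 at -0.10 and PCNA at 0.04 on the log2 scale. At the preset correlation the mitosis list passed as higher without donor A (camera adjusted p = 1.41e-04) and turned lower without donor B (0.738), and in the main comparison its estimated correlation of 0.668 gave an adjusted p of 0.897. DNA replication did not pass without donor A (0.0671).

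In the stress and metabolic lists no member passed in limma, while voom passed SLC7A11 (adjusted p = 0.00192), HMOX1 (0.00695), ATF3 (0.0353) and IER3 (0.00315). The NRF2 targets (camera adjusted p = 0.728) held HMOX1 at 0.36 and the cystine transporter SLC7A11 at -0.64 on the log2 scale, and the ATF4 and unfolded protein response list (0.852) held ATF3 at -0.39 besides SLC7A11. The p53 targets (0.337) held ZMAT3 at -0.26 and CDKN1A at -0.18, cholesterol synthesis (0.485) held INSIG1 at -0.27, and the hypoxia response (0.903) held PFKFB3 at 0.23. The immediate early and heat shock genes (0.337) held IER3 at -0.49, and replication-dependent histones had an adjusted p of 0.968. The mixed form of fry passed for the NRF2 (adjusted p = 0.0348), ATF4 (0.0348) and immediate early (0.0227) lists. It did not for the p53 (0.192), cholesterol (0.382), hypoxia (0.174) and histone (0.978) lists.

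Nor did lists of endothelial function pass in camera. The mixed form of fry passed for tip cell and angiogenesis (adjusted p = 0.0474), coagulation and fibrinolysis (0.0227), shear stress and KLF2 (0.0227) and TGF beta and mesenchymal transition (0.0287). It did not for junctions and barrier (0.178) or the inflammatory genes (0.341). The tip cell and angiogenesis list (adjusted p = 0.705) was mixed, with 6 of 15 genes higher and 4 lower when adjusted over the list alone, among them PGF at 0.51 and NRP2 at -0.45, both called by voom. Coagulation and fibrinolysis (0.83) held PLAU at 0.34 and TFPI, the tissue factor pathway inhibitor, at -0.37, both past the threshold in voom (adjusted p = 0.00788 and 0.00877). VWF of this list, at -0.27, also passed in voom (adjusted p = 0.0403). Below the filter, F3, tissue factor itself, had a voom log2 fold change of -1.72 ± 0.32 (adjusted p = 0.02605). The shear stress and KLF2 list (0.313) and the inflammatory adhesion and chemokine genes (0.337, CXCL1 at 0.36) had no member past the threshold in limma. Nor had TGF beta and mesenchymal transition (0.705, TAGLN at 0.40) or junctions and barrier (0.279, CTNNA1 at -0.16). Voom passed TAGLN (adjusted p = 0.035) and, of the shear stress list, HMOX1. It also passed CYP1B1 of that list, below the filter, at -5.85 (adjusted p = 3.54e-05).

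Few markers of other cell types reached the filter. None of the fibroblast and stromal or erythroid markers did, 1 leukocyte marker did (FCER1G, 0.414 ± 0.148 and 0.508 ± 0.165 FPKM), and 2 smooth muscle and pericyte markers did, ACTA2 (9.47 ± 3.31 and 9.70 ± 3.01 FPKM) and TAGLN (20.6 ± 2.54 and 27.2 ± 3.12 FPKM). Below the filter, over genes with 20 or more reads, camera on the voom values placed the 11 listed fibroblast and stromal markers lower under SR1 (adjusted p = 0.027), against 0.147 on FPKM with no filter. LUM, a matrix proteoglycan, had 54, 108 and 68 reads in vehicle and 27, 48 and 47 under SR1 (voom log2 fold change -1.08, adjusted p = 0.0484), and COL3A1 had 56, 708 and 26 against 15, 131 and 24 (-2.26, 0.0745). The authors' deposited table gives -1.07 for LUM and -1.90 for COL3A1, with FDR of 0.00404 and 1.72e-12. Of the epithelial markers 4 keratins were tested, with KRT19 at 0.25 and KRT18 at 0.23 on the log2 scale. None of the markers above the filter passed in limma, and TAGLN did in voom. The 13 mitochondrially encoded genes were all positive (median log2 fold change 0.28; camera adjusted p = 0.095) and none passed in limma. The list passed camera without donor B (1.59e-09), without the donor term (0.00536), with one sum (0.00265) and in voom on genes with 20 or more reads (0.027), but turned lower without donor A (0.0671), and in the main comparison its estimated correlation of 0.984 gave an adjusted p of 0.897. Across donors it varied, with MT-CO2 at 1.22, -0.29 and 0.10 in donors A, B and C. Reads were recovered for 11 of the 13 genes, so the voom fits and the shares of reads given here cover only those 11. Their share of recovered reads was 1.82% in the vehicle and 3.91% in the SR1 library of donor A, against 2.77% to 4.07% in the other 4 libraries.

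In genome coordinates (GRCh38, GENCODE release 29), CYP1A1 (ENSG00000140465) lies on chromosome 15 from 74719542 to 74725610 on the minus strand, VIPR1 (ENSG00000114812) on chromosome 3 from 42489299 to 42537573 on the plus strand, ITGA11 (ENSG00000137809) on chromosome 15 from 68296533 to 68432162 on the minus strand, and GJA4 (ENSG00000187513) on chromosome 1 from 34792998 to 34795747 on the plus strand. PTGS2 (ENSG00000073756) and PLA2G4A (ENSG00000116711) lie on chromosome 1, at 186671791 to 186680427 and 186828953 to 186988981.

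The authors' deposited table held 158 genes with an FDR under 0.05, of which 39 were higher and 119 lower under SR1. All 17 genes changed here were among them, in the same direction, and 116 of the 158 were among the genes tested here. Of the others, 32 lay below the filter and 10 had no row in the FPKM table. Across the genes tested, which are not independent replicates, the log2 fold changes here and in the authors' deposited table correlated with r = 0.837.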

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

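The tests in this part were chosen after the results were seen, except the list tests and the left-out donors.

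Signals in data outside the main comparison came from the authors' deposited table, where 10 genes with no row in the FPKM table had an FDR under 0.05. Those lower under SR1 were VIPR1-AS1 (log2 fold change -3.39), AC009731.1 (-2.75), CYP1B1-AS1 (-2.33), AC027309.1 (-1.27), SERPINB10 (-0.87), HCG20 (-0.46) and AC093866.1 (-0.44). Those higher were PLA2G4C-AS1 (0.54), AC113554.1 (0.49) and AL049780.1 (0.42). They were not tested here.

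Several of these genes are named as antisense partners of genes on the opposite strand, so the authors' deposited comparison was set against the reads recovered from the FPKM table. Genes in both were kept only above a minimum abundance in the authors' comparison, which left 13295. Of these, 3854 share exon bases with a listed gene on the opposite strand. Among the overlapping genes, 18.2% lay 2-fold or more above their recovered level in the authors' comparison, against 5.38% of the rest, a ratio of 3.39. In the 703 overlapping genes with that excess, the median excess was 3.01 on the log2 scale. It was 0.52 after the overlapping part of the neighbour's signal was added. Genes with few recovered reads were kept only where the authors' level was high, so both shares and the median excess may be inflated. Reads of the opposite strand may be counted in the authors' comparison, but the bounds set for the test (a ratio of 10 and a remainder under 0.5) were missed. The excess without such an overlap is left unexplained. Of 6 called genes with both features (WTAPP1, IER3-AS1, SLC7A11-AS1, AC015712.2, AC009139.1 and C10orf55), 3 had a fold change in the recovered reads more than 2 SE from the authors' value. Only 1, WTAPP1, passed the threshold the same way. In donors A, B and C it had 8, 166 and 55 recovered reads in vehicle, against 27849, 697339 and 268545 for MMP1. The authors' log2 fold changes were -1.915 for WTAPP1 and -1.916 for MMP1. Whether the few reads of WTAPP1 came from MMP1 on the opposite strand was not tested. WTAPP1 therefore decides nothing, and co-regulated antisense transcripts stay open too.

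The mitochondrially encoded genes parted the donors, with a median log2 fold change of 1.08 in donor A, -0.31 in donor B and 0.06 in donor C. The tables argue against library depth as the source, since 2 libraries no deeper than the vehicle library of donor A had a higher mitochondrial share of reads. Nor did scaling shift the pair as a whole, with a median of -0.017 (log2) over the other genes of donor A. A low vehicle library remains a candidate source, since its share was 1.82% while the SR1 library of donor A, at 3.91%, lay within the 2.77% to 4.07% of the other donors. All these shares cover only the 11 of 13 mitochondrially encoded genes whose reads were recovered. A response to SR1 in donor A alone was not tested, since each donor has 1 library per treatment.

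The type I interferon list may rest on 1 donor, since without donor B its camera adjusted p was 0.362, against 1.41e-04 without donor A and 0.0044 without donor C. All 15 tested members averaged 100 or more reads per library, so restricting the list to them changed nothing (camera adjusted p = 0.00428, fry adjusted p = 0.599). That test says nothing about genes with few reads. With the low members included, 23 members passed camera with no filter (adjusted p = 8.00e-05) and in voom on genes with 20 or more reads (4.05e-07). Both used the preset correlation and all donors, so they do not tell whether donor B carries the list. Of the 8 members below the filter, MX2, IFIT1, OASL and XAF1 had higher FPKM under SR1 in all 3 donors, while IFIT2, IFI44L, RSAD2 and CXCL11 went both ways. None of the 8 passed in voom, where MX2 had the lowest adjusted p, 0.0876. A biological response shared by the donors stays open.

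The 6 libraries can be split into 3 and 3 in 10 ways, the real split included, too few for a share under 0.05. The real split called 17 genes, and the highest other 353, with 3 splits at 17 or more, the real split included. Both of the others part only the pair of donor A, so that with the donor term they set 1 library against 1, SR1 against vehicle in that donor, and without the donor term they call 0 genes. Such a count points to a structure of the samples, here at most that the 2 libraries of donor A differ. Among the 4 splits that part all 3 pairs, the real split called 17 genes and the highest other 0. In 5 of the 10 splits some direction held as many calls as the 1 gene higher under SR1, and in 3 as many as the 16 lower, the highest other being 340 for both. AHR target genes past the threshold numbered 1 in the real split, the only 1 of the 10 to reach that count, with 0 as the highest other. For the gene lists, 2 of the 10 splits called 5 lists, namely the real split and another that also parts all 3 pairs.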

How the results depend on the processing

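The voom fits and the AHR list without CYP1A1 were added after the data were seen. Genes changed, higher and lower under SR1 numbered 17, 1 and 16. Without the donor pairing (no replicate block) they were 1, 0 and 1, with no filter 9, 0 and 9, with FPKM of 1 or more in all libraries 81, 20 and 61, and with each library scaled to one sum 170, 40 and 130. Limma without trend and robust estimation gave 5, 0 and 5, a threshold of 0.1 gave 64, 13 and 51, voom on the recovered reads gave 136, 30 and 106, and voom on genes with 20 or more reads gave 152, 32 and 120. With a pseudocount of 1 and with median ratio scaling 14 and 13 genes were called, 0 of them higher. Leaving out each donor gave 0 to 119 changed, 0 to 29 higher and 0 to 90 lower; without donor C limma called 0 genes with 911 at an unadjusted p under 0.05. The 17 genes were all among those called without donor A, with one sum, and by both voom fits, and 11 of them among those of the stricter filter. AHR targets past the threshold were 1, with 0 at a pseudocount of 1 and without CYP1A1, 3 with the stricter filter, 4 with one sum, a threshold of 0.1 or voom, 5 with voom on 20 or more reads, and 0 to 4 with a donor left out. Gene lists past the threshold were 5, with 3 to 5 when a donor was left out, and stayed within 1.5 times in the other settings. Apart from the fewer donors and the threshold, the cause was not tested. Over single named genes and settings, 1382 values kept their side of the threshold, 123 moved past it and 56 no longer passed. Among values past the threshold in either setting, 0 reversed in sign. A change of sign short of the threshold in both settings was counted as kept. The median log2 fold change of all tested genes was 0.02 with median ratio scaling and -0.04 with one sum, against 0.0092 in the main comparison. Depth limits the low genes most, such as CYP1B1 with 1 to 5 reads under SR1.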

Other observations

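The genes and groups in this part, and the tests on them, were chosen after the values were seen.

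Some genes of retinoid metabolism had lower values under SR1 and others did not. ALDH1A1, a retinal dehydrogenase, had 48.1 ± 25.0 FPKM in vehicle and 19.9 ± 8.43 FPKM under SR1 (log2 fold change -1.19 ± 0.116), which limma did not call on FPKM (adjusted p = 0.0711) and voom on the recovered reads did (0.00197). CYP26B1, which degrades retinoic acid, had 0.683 ± 0.419 and 0.261 ± 0.0917 FPKM (voom log2 fold change -1.35 ± 0.177, adjusted p = 0.0022), and DHRS3, a retinal reductase, 3.16 ± 0.503 and 2.15 ± 0.552 FPKM (voom -0.56 ± 0.104, adjusted p = 0.0252). Of 13 tested members, the 10 that the authors' deposited table does not call went both ways in limma and none passed, with 6 negative, among them PLAAT4 (-0.33), RARB (-0.29) and RDH10 (-0.07), and 4 positive, RARG (0.08), ALDH1A2 (0.05), RARA (0.04) and RDH14 (0.025).

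MMP1, the interstitial collagenase, had 3029 ± 3179 FPKM in vehicle and 951 ± 1003 FPKM under SR1, with log2 fold changes of -2.52, -1.68 and -1.59 in donors A, B and C. Its level varied widely between donors, a difference that the donor term takes out of the comparison. Neither limma (adjusted p = 0.213) nor voom (0.328) called MMP1, while the authors' deposited table gives an FDR of 4.25e-07. MMP2 had log2 fold changes of -0.30, -0.233 and -0.319 in donors A, B and C. Limma did not call MMP2 (adjusted p = 0.141) and voom did (-0.284 ± 0.052, adjusted p = 0.0239). No other secreted metalloproteinase or inhibitor of the group passed in either. Of the enzymes around PLA2G4A and PTGS2, PLA2G4C had 5.52 ± 3.11 and 8.33 ± 5.57 FPKM (voom log2 fold change 0.53 ± 0.083, adjusted p = 0.011), opposite in sign to PLA2G4A.

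A hypothesis for each group was that the whole group, and not only its called members, may be lower under SR1. Fry was run on the members that the authors' deposited table does not call. The direction was upward for 7 members of prostanoid and leukotriene synthesis, and downward for 10 members of retinoid metabolism and for 5 secreted metalloproteinases and their inhibitors. Adjusted over the 3 groups, limma's fry gave an adjusted p = 0.21 for each. Their median log2 fold changes were 0.01, -0.005 and -0.015. Because the members were picked by not having been called for the same change, which draws the rest toward no shift, these tests decide nothing, and the hypotheses stay open.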
